A study of Mus musculus with 12 samples.

How the data were processed

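Messenger RNA was measured in sorted haematopoietic stem cells of mice labelled TG, which carry an inducible Trmt6/Trmt61a transgene, and of WT mice. Small RNA was measured in KSL cells (lineage-negative cells positive for Kit and Sca1) of old and young C57BL/6 mice, with and without AlkB, an enzyme that removes base methylation from RNA before sequencing. The 12 libraries fell into 6 groups of 2, taken from the sample labels. The labels do not say that replicates of a group came from separate animals, so a p-value here may measure technical spread.

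For the RNA-seq libraries the authors named Trim Galore, HISAT2, featureCounts and DESeq2 with the mouse build mm10. The deposited gene table gave RPKM (reads scaled to gene length and library depth) for 25239 genes in the 4 libraries. The denominators of these RPKM values are not given in the sources used here. A second deposited gene table held 9 columns of per-sample values whose names matched no single sample, and it was not used. The planned edgeR test needs counts, so its written substitute for normalized values, limma-trend, was used as the main test. Absolute depth was therefore unknown for these libraries, and no counting interval was computed for them. Low RPKM values fell in whole steps whose ratios put TG replicate 2, WT replicate 1 and WT replicate 2 at 0.987, 1.39 and 0.925 times the depth of TG replicate 1. Those steps were shared by 63 of 315, 30 of 267 and 60 of 269 low genes, so the ratios are rough.

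For the small RNA libraries the authors named Trim Galore 0.6.6 and DESeq2 with mm10; the aligner is not given in the sources used here. The deposited fragment tables gave counts of each distinct sequence of 15 to 50 nt and its RPM, scaled to a library total larger than the listed reads. Only sequences above about 1 RPM were listed, the smallest listed values being 1.02 to 1.13 RPM, so a sequence missing from a library was not necessarily absent. Listed reads were 7462772 and 6703269 in old replicates 1 and 2, and 4281841 and 3288320 in young replicates 1 and 2. They made up 76.3% to 83.6% of library totals of 9780365, 8572178, 5321408 and 3935119 reads. The deposited m1A tables (m1A is N1-methyladenosine) gave counts of each base at listed adenines of tRNA in a pair of libraries that the file headers call input and IP. They also gave, per the file headers, the percent of reads not reading A, and the ratio of IP to input misreading. Recomputing that percent from the base counts gave the same values within 0.01 points. The labels do not say which of the input and IP libraries had been treated with AlkB. Sites were listed only where IP misreading exceeded input by a ratio of at least 3.00 and by at least 10.5 points. The median coverage of listed sites in the IP library was 44392, 28488.5, 23983 and 20973.5 reads in old replicates 1 and 2 and young replicates 1 and 2.

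TG and WT were compared by limma 3.58.1 (trend on mean expression) on log2(RPKM + 1), a pseudocount of 1, over the 10433 genes with an RPKM of at least 1 in at least 2 libraries. Sets of genes were tested by camera with a preset inter-gene correlation of 0.01. They comprised 25 gene lists, of which 24 had members among the tested genes. The lists, tests, comparisons, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made after values were seen. Fragments were summed into classes by isoacceptor (amino acid and anticodon) and kind. The kinds were 3′ fragments of 30 to 50 nt, 3′ fragments of 15 to 29 nt, 5′ fragments of the same length ranges, and internal fragments. Classes and single sequences were compared between ages by the edgeR 4.0.16 quasi-likelihood test with TMM factors of 0.983, 0.967, 1.11 and 0.947 after filterByExpr. Fragments per class are given as CPM, counts scaled to the tRNA reads of each library and these factors. The percent of reads not reading A in the IP library was taken as the m1A level. Levels were compared by a quasi-binomial logistic model per site at coverage of at least 20 reads in each library. Benjamini-Hochberg adjusted p-values were used with a threshold of 0.05, and all tests were two-sided. Library shares and mean levels were compared by exact permutation tests, for which 2 against 2 libraries cannot give a p below 0.333. Permutation tests over isoacceptors used 100000 resamples. Shares of reads carry 95% Wilson intervals, which cover counting error only. The other software was R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

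The rule for named genes took Trmt6, Trmt61a, Ripk1, Ripk3, Mlkl and Dcaf1 in every case. It added up to 12 genes with the highest and 12 with the lowest fold change among genes past the threshold, and up to 4 members of smallest p from each list. For fragments it took up to 10 classes past the threshold in each direction, each class of Leu-CAG, and the 5 highest and 5 lowest single sequences with at least 100 reads. For m1A it took the 10 sites with the largest rise, the 10 with the largest fall and each site of Leu-CAG.

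The tests were checked on simulated data whose spread was a trend or median over the features of these libraries. At a log2 change of 3, limma recovered 27.0% of changed genes, and at 5 it recovered 79.0%, with 3 unchanged genes called. For fragment classes edgeR recovered 68.4% at a log2 change of 1 and 100% at 2, with 3 unchanged classes called. For sequences listed in every library it recovered 18.2% and 95.0% at those changes, with 8 unchanged sequences called. The quasi-binomial model recovered 46.7% of sites at a logit change of 1 and 86.7% at 2, with 1 unchanged site called. Limma on the empirical logit recovered 100% at both, with 3 unchanged sites called. Every simulated site had the same spread, the median over sites, so the check does not show how limma fares where sites differ in spread.

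Alternatives covered the filter on low values, the pseudocount, the scaling, other tests, the grouping of fragments, the coverage minimum, the replicate number as a block and the removal of each library in turn. Where a removal left 1 library in a group, that library was assumed to vary like the others of the fit. The spread of its group was then not measured. Counts and p-values of such fits therefore show only how results depend on single libraries, and are not calls.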

Results

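RNA-seq libraries were made by Smart-seq2, a full-length cDNA method for few cells, from 200 sorted haematopoietic stem cells (lineage-negative, Sca1 and Kit positive, CD34 and CD135 negative). The donors were labelled TG or WT, with 2 libraries each, and all had received doxycycline for 4 weeks. Small RNA under 200 nt came from KSL cells of old mice (24 months) and young mice (3 months in the AlkB-treated libraries, 8 weeks in the untreated ones), with 2 libraries per age and treatment. The sum of RPKM was 738732 and 598665 in TG replicates 1 and 2, and 592049 and 602231 in WT replicates 1 and 2. The fragment libraries held 7462772 and 6703269 listed reads in old replicates 1 and 2, and 4281841 and 3288320 in young replicates 1 and 2. The m1A libraries held 25478110, 18455061, 17809677 and 15422645 IP base calls summed over listed sites, in old replicates 1 and 2 and young replicates 1 and 2.

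The comparison of TG with WT asked what an inducible Trmt6/Trmt61a transgene does to stem cell transcripts. The products of these genes form the enzyme that makes m1A at position 58 of tRNA. Trmt6 (chromosome 2, 132804207 to 132816054, GRCm38) was at 17.8 ± 19.2 RPKM in TG and 11.9 ± 9.10 in WT (SD, n = 2 each). Trmt61a (chromosome 12, 111678105 to 111683902) was at 18.8 ± 19.8 in TG and 8.26 ± 4.36 in WT. Neither passed the test, with log2 fold changes of 0.23 (SE 1.08, limma adjusted p = 0.987) and 0.67 (SE 1.01, adjusted p = 0.931). Trmt6 was high in TG replicate 2 (31.4) and low in TG replicate 1 (4.28), and Trmt61a was high in TG replicate 1 (32.8) and low in TG replicate 2 (4.74). In WT, Trmt6 was at 5.42 and 18.3 and Trmt61a at 11.3 and 5.18. Without TG replicate 2 the Trmt6 fold change was −1.07, and without TG replicate 1 that of Trmt61a was −0.60. The labels TG and WT are therefore used as names only, and not as measured expression of the transgene.

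Ripk1, Ripk3 and Mlkl, the kinases and pseudokinase of necroptosis, varied more within TG than between genotypes. Ripk1 was at 7.71 and 0.404 RPKM in TG and 8.37 and 4.76 in WT. Ripk3 was at 25.02 and 5.97 in TG and 13.8 and 11.9 in WT, and Mlkl at 0.698 and 23.3 in TG and 3.74 and 3.56 in WT. Their log2 fold changes of −1.07, −0.04 and 0.46 became 0.25, 0.91 and −1.45 without TG replicate 2, and those of Ripk3 and Mlkl were −0.99 and 2.38 without TG replicate 1. Dcaf1, the substrate receptor of a CUL4 ubiquitin ligase, was at 3.76 and 2.84 in TG and 6.70 and 5.10 in WT, a log2 fold change of −0.68 (SE 0.74, limma adjusted p = 0.895). Casp8, the protease that restrains necroptosis, was at 38.7 ± 0.210 in TG and 10.4 ± 2.09 in WT (SD, n = 2 each), a log2 fold change of 1.82 (SE 0.52, limma adjusted p = 0.617).

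Over all genes, 0 of 10433 passed the threshold by limma, the smallest adjusted p being 0.617, and no other tool was run on the RPKM values. At an unadjusted p under 0.05 there were 828 genes, 265 higher and 563 lower in TG, where 522 would be called by chance. The TG libraries both lay above both WT libraries for 1895 genes and below for 2003, where chance gives 1739 in each direction, 33.3% of genes in all. The smallest p-values, picked after they were seen, belonged to histone genes and others. H2ac15 was at 3.26 ± 0.0297 RPKM in TG and 138 ± 22.8 in WT (SD, n = 2 each), and H4c9 at 0.481 ± 0.223 and 64.0 ± 33.3. Crip2 was at 0.121 ± 0.0583 and 44.9 ± 22.9, and Mpv17l2, a mitochondrial ribosome assembly factor, at 163 ± 9.79 and 23.8 ± 2.48. The TG libraries correlated with each other across genes at 0.719 and the WT libraries at 0.898. A TG with a WT library correlated at 0.769 to 0.819, so each TG library was closer to WT than to the other. TG replicate 2 had 602 of the tested genes at 0 and TG replicate 1 had 274, against 79 and 82 in WT. Xist, transcribed from the inactive X chromosome of female cells, was at 4.61 and 8.31 RPKM in TG and 0.0672 and 0 in WT, while the Y-linked Ddx3y was above 0 in each, at 3.01 and 1.28 in TG and 5.00 and 4.15 in WT. Xist thus split as the labels did, so a share of female cells in the TG libraries alone would be confounded with every difference between TG and WT given here. Without TG replicate 1, 796 genes passed the threshold (207 higher, 589 lower), and without TG replicate 2, 69 did (8 higher, 61 lower). Without WT replicate 1, 1 gene passed, Jchain, at a log2 fold change of −4.96 (adjusted p = 0.00344), and without WT replicate 2, 0 did.

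**Figure D1:**
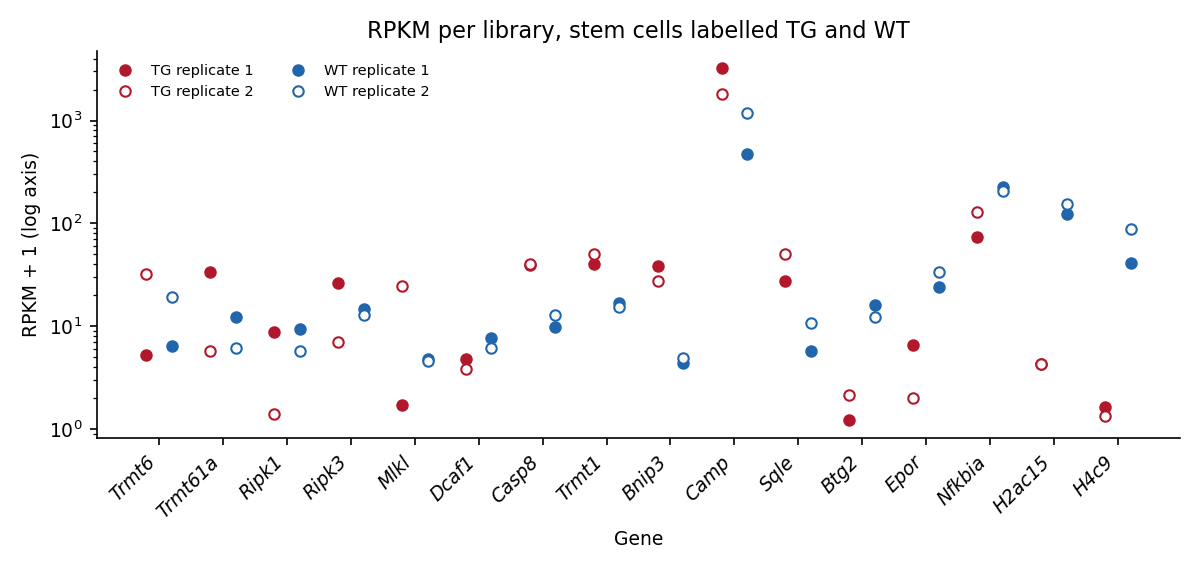
RPKM + 1 on a log axis for 16 genes, with each library as a point (red TG, blue WT; filled replicate 1, open replicate 2). Trmt6 and Trmt61a overlap between the labels, while Casp8, Bnip3, H2ac15 and H4c9 do not.

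Cytosolic ribosomal protein genes rose as a list in TG, at a median log2 fold change of 0.25 over 81 tested genes (camera adjusted p = 0.00405). The call was lost when the correlation among the genes was taken from the data, at adjusted p = 0.904 with an estimated correlation, so no camera call held there. Of the 81 genes, 26 lay above WT in both TG libraries and 2 below, against 13.5 expected by chance for each. Rpl22 was at 490 ± 89.9 RPKM in TG and 286 ± 50.2 in WT (SD, n = 2 each). Rps4l was among the exceptions, at 14.7 ± 1.52 and 67.2 ± 8.37. The call was lost without TG replicate 1 (adjusted p = 0.891) and without WT replicate 2 (0.115), and the median was 0.50 without TG replicate 2 (adjusted p = 2.04e-06). Genes of the mitochondrial respiratory chain had a median of 0.17 over 74 genes (camera adjusted p = 0.0805), with Ndufa4 at 995 ± 60.8 in TG and 538 ± 99.4 in WT and Cox5b at 263 ± 3.84 and 508 ± 67.9. That list passed without TG replicate 2 (median 0.49, adjusted p = 0.000614) and with all libraries under median-ratio scaling, chosen after seeing the data (adjusted p = 0.0315), and lost its direction without TG replicate 1 (adjusted p = 0.899). With the correlation estimated from all libraries (0.327, against the preset 0.01) its adjusted p was 0.904.

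Histone genes had a median log2 fold change of −0.30 over 35 tested members (camera adjusted p = 0.0611). None of them passed over all genes tested, and 3 passed when adjusted over the list alone. At an unadjusted p under 0.05, 5 were lower and 0 higher. Hist1h2an was at 1.71 ± 0.883 RPKM in TG and 25.9 ± 3.25 in WT, and H2bu2 at 0.627 ± 0.887 and 13.5 ± 5.52 (SD, n = 2 each). Histone genes share near-identical sequence, so reads between members are uncertain. At the preset correlation the histone list passed without TG replicate 2 (median −0.55, adjusted p = 0.000614), without WT replicate 1 (−0.63, 0.00725) and without WT replicate 2 (−0.40, 0.0129), and not without TG replicate 1 (adjusted p = 0.891). With all libraries it passed with the replicate number as a block (adjusted p = 0.0381), and its adjusted p was 0.904 with an estimated correlation of 0.030. In each of the other lists, 0 members passed over all genes tested and 0 when adjusted over the list alone.

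Genes of cholesterol synthesis had a median log2 fold change of 0.37 over 17 members (camera adjusted p = 0.0526; adjusted p = 0.904 with an estimated correlation). Sqle, which makes squalene epoxide, was at 37.6 ± 15.9 RPKM in TG and 7.28 ± 3.56 in WT, and Fdft1 at 14.2 ± 2.43 and 3.29 ± 1.33 (SD, n = 2 each). That list passed without WT replicate 2 (median 0.78, adjusted p = 0.0202), and with all libraries under median-ratio scaling (0.0413) and with the replicate number as a block (0.0381). The p53 target list had a median of −1.08 over 10 members (camera adjusted p = 0.0611), with Gadd45a at 2.11 ± 2.53 in TG and 14.4 ± 7.89 in WT and Bbc3 at 1.05 ± 1.12 and 5.60 ± 0.00277. It passed under median-ratio scaling at the preset correlation (adjusted p = 0.0413), and its adjusted p was 0.904 with an estimated correlation of 0.0030. Immediate early genes, which also respond to cell dissociation, had a median of −0.85 over 10 members (camera adjusted p = 0.130). Btg2 was at 0.675 ± 0.660 in TG and 13.0 ± 2.59 in WT, and Junb at 5.32 ± 5.85 and 33.8 ± 15.4. That list passed without TG replicate 2 (median −1.97, adjusted p = 0.00102) and without WT replicate 2 (−0.56, 0.0129), both at the preset correlation, while with all libraries and an estimated correlation of 0.309 its adjusted p was 0.904. The inflammatory NF-kappaB list had a median of −0.96 over 10 members (camera adjusted p = 0.148), with Nfkbia, the inhibitor of the pathway, at 101 ± 39.5 and 216 ± 13.4.

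**Figure D2:**
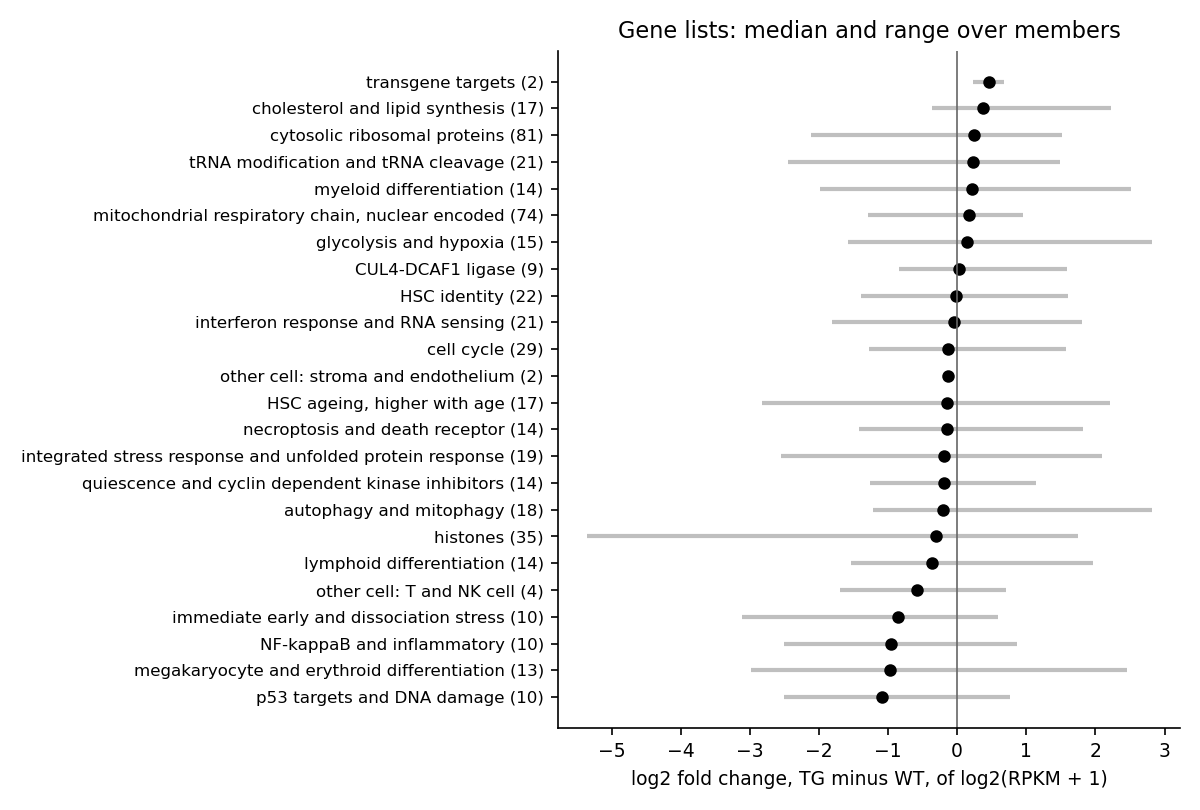
Median log2 fold change (TG minus WT, point) and range from lowest to highest member (bar) for 24 gene lists, with the number of tested members in brackets. Medians run from −1.08 for p53 targets to 0.45 for the transgene targets, and the ranges of all lists but the transgene targets and the stroma and endothelium list cross 0.

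Lists of stem cell identity and lineage did not pass. Stem cell identity genes had a median log2 fold change of −0.02 over 22 members (camera adjusted p = 0.797), with Meis1 at 61.5 ± 5.67 RPKM in TG and 35.7 ± 6.73 in WT and Esam at 57.3 ± 42.8 and 15.4 ± 2.06 (SD, n = 2 each). Genes reported to be higher in aged stem cells had a median of −0.15 over 17 members (adjusted p = 0.874), with Clu at 0.888 ± 1.26 and 11.3 ± 4.72. Myeloid genes had a median of 0.21 over 14 members (adjusted p = 0.203), with Camp, a granule peptide, at 2519 ± 985 and 832 ± 509 and Ltf at 93.9 ± 23.7 and 24.5 ± 17.98. The myeloid list passed without WT replicate 2 at the preset correlation (median 0.84, adjusted p = 1.96e-05), while with all libraries and an estimated correlation of 0.547, the highest of the 24 lists, its adjusted p was 0.904. Lymphoid genes had a median of −0.37 over 14 members (adjusted p = 0.993), with Vpreb1 at 146 ± 32.6 and 40.7 ± 26.9 and Il7r at 0.101 ± 0.0847 and 2.20 ± 0.354. Megakaryocyte and erythroid genes had a median of −0.97 over 13 members (adjusted p = 0.507), with Epor at 3.24 ± 3.18 and 27.8 ± 6.74 and Pf4 at 138 ± 70.3 and 49.0 ± 3.60. Markers of T and NK cells had a median of −0.58 over 4 members (adjusted p = 0.728) and those of stroma and endothelium one of −0.13 over 2 (adjusted p = 0.944). Cell cycle genes had a median of −0.13 over 29 members (adjusted p = 0.728), with Mcm2, of the replicative helicase, at 80.7 ± 53.005 and 23.4 ± 3.06. The cell cycle list passed upward without WT replicate 2 at the preset correlation (median 0.45, adjusted p = 0.0221), while with all libraries and an estimated correlation of 0.2895 its adjusted p was 0.9497. Quiescence genes had a median of −0.20 over 14 members (adjusted p = 0.902), with Foxo3 at 0.0674 ± 0.0323 and 1.56 ± 0.101.

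Genes of tRNA modification and cleavage had a median log2 fold change of 0.23 over 21 members (camera adjusted p = 0.498). Trmt1, which makes dimethylguanosine in tRNA, was at 44.0 ± 7.14 RPKM in TG and 14.95 ± 0.939 in WT, Trmt10c at 29.4 ± 1.01 and 10.4 ± 4.42, and the demethylase Alkbh3 at 5.18 ± 5.61 and 25.3 ± 7.20 (SD, n = 2 each). The CUL4-DCAF1 ligase list had a median of 0.03 over 9 members (adjusted p = 0.902). Death receptor and necroptosis genes had a median of −0.15 over 14 (adjusted p = 0.797), interferon and RNA sensing genes one of −0.05 over 21 (adjusted p = 0.583), and stress response genes one of −0.18 over 19 (adjusted p = 0.902). Ifi27l2a was at 47.9 ± 17.8 in TG and 12.7 ± 2.81 in WT, and Chac1 at 4.14 ± 3.25 and 0.0738 ± 0.0209. Autophagy genes had a median of −0.20 over 18 members (adjusted p = 0.944), and glycolysis and hypoxia genes one of 0.14 over 15 (adjusted p = 0.728). Bnip3, a mitophagy receptor in both lists, was at 31.8 ± 7.95 and 3.62 ± 0.377. The transgene targets, Trmt6 and Trmt61a, had a median of 0.45 (adjusted p = 0.797).

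By fry, 0 of the 24 lists passed for movement one way on balance, the smallest adjusted p being 0.635. Its mixed test, which asks for change in either direction, passed for histones (adjusted p = 0.00136), autophagy (0.00751) and glycolysis and hypoxia (0.0101). Neither fry test compares a list with other genes. Before adjustment, camera gave a p under 0.05 for 7 lists, those of ribosomal, respiratory chain, cholesterol, p53, histone, immediate early and NF-kappaB genes, and fry for 1, the cholesterol genes. The camera direction was up while the median was below 0 for necroptosis (mean −0.05), interferon (mean 0.10), stem cell identity (mean −0.02), cell cycle (mean −0.01) and autophagy (mean −0.0030) genes. For the CUL4-DCAF1 list the median was 0.03, the mean −0.03, the camera direction up and the fry direction down.

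The AlkB-treated libraries asked which tRNA fragments differ between old and young cells. The library method adds a linker to the 3′ end of the RNA and an adaptor to the end of the cDNA, so a fragment with the tRNA 3′ end can mark either cleavage or a stop of the reverse transcriptase. The 3′ fragments of 30 to 50 nt made up 64.1% and 65.2% of tRNA reads in old replicates 1 and 2, and 60.2% and 67.0% in young replicates 1 and 2. Wilson half-widths were 0.0356 to 0.0523 points. The old mean exceeded the young mean by 1.05 points (exact permutation p = 1), and without young replicate 1 the difference was −2.35 points. The 3′ fragments of 15 to 29 nt were at 13.6% ± 0.684 in old and 13.3% ± 3.14 in young (SD, n = 2 each), a difference of 0.361 points (exact permutation p = 1) that was −1.86 points without young replicate 2 and −0.122 without old replicate 2. The 5′ fragments of 30 to 50 nt were at 3.03% ± 0.302 and 3.33% ± 0.239 (−0.300 points, exact permutation p = 0.667). Those of 15 to 29 nt were at 0.667% ± 0.0398 and 0.762% ± 0.336 (−0.0953 points, exact permutation p = 1), with a difference of 0.143 points without young replicate 1. Internal fragments were at 18.01% ± 1.18 and 19.0% ± 1.10 (−1.02 points, exact permutation p = 0.667). With 1 library left out, the difference ranged from −0.513 to −0.0860 points for 5′ fragments of 30 to 50 nt, and from −1.85 to −0.178 points for internal fragments. As shares of the different sequences in place of reads, the differences were 0.515 and 0.326 points for the longer and shorter 3′ fragments, −0.0131 and −0.00455 points for the longer and shorter 5′ fragments and −0.823 points for internal ones. With only fragments of at least 10 counts they were 0.823, 0.316, −0.306, −0.0933 and −0.740 points in that order.

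Among fragment classes, the 3′ fragments of 30 to 50 nt of Leu-CAG and Tyr-GTA tRNA had the highest old-to-young ratios of the classes with the smallest p. Leu-CAG was at 9675 ± 948 CPM in old and 4866 ± 104 in young (SD, n = 2 each), a log2 fold change of 0.99 (SE 0.14). Tyr-GTA was at 19806 ± 1323 and 9948 ± 426, a log2 fold change of 0.99 (SE 0.15), and its internal fragments were at 4323 ± 209 and 2277 ± 134, one of 0.92 (SE 0.13). All had an edgeR adjusted p of 0.0804, the smallest of the 293 classes, so 0 classes passed, with 18 at an unadjusted p under 0.05 (9 higher, 9 lower) where 14.7 would be called by chance. By DESeq2, 5 classes passed. These were the 3 above (adjusted p = 3.41e-06, 3.07e-06 and 1.20e-05), which rose by that test, and the 5′ fragments of 30 to 50 nt of Trp-CCA (log2 −0.78, adjusted p = 0.00396) and of Ser-CGA (adjusted p = 0.0287), which fell by it. The Ser-CGA class was not listed in either old library and had 24 and 23 reads in the young ones. Over the alternatives that kept all libraries, the adjusted p of these 5 classes ran from 3.07e-06 to 0.571. The edgeR count was 65 (38 higher, 27 lower) without young replicate 1, 49 (25 higher, 24 lower) without young replicate 2, and 0 without either old library.

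Summed as classes, other leucine tRNAs had smaller differences in their 3′ fragments of 30 to 50 nt. Single sequences of Leu-CAA are given below. Leu-CAA was at 9649 ± 609 CPM in old and 6791 ± 734 in young, and Leu-TAA at 9193 ± 26.7 and 6026 ± 1420 (SD, n = 2 each), with log2 fold changes of 0.51 and 0.61. These were 0.62 and 0.39 without young replicate 1 (adjusted p = 2.79e-06 and 0.00614) and 0.37 and 0.85 without young replicate 2 (0.00750 and 3.56e-10). Fragments that match both Leu-CAA and Leu-CAG were at 5609 ± 478 and 3860 ± 669, a log2 fold change of 0.54 (edgeR adjusted p = 0.679), 0.73 without young replicate 1 (2.07e-06) and 0.35 without young replicate 2 (0.0412). Within Leu-CAG, 3′ fragments of 15 to 29 nt had a log2 fold change of 0.61, internal fragments one of 0.28, 5′ fragments of 30 to 50 nt one of −0.30, and 5′ fragments of 15 to 29 nt one of 0.11. The first was 1.10 without young replicate 1 (adjusted p = 5.55e-08) and 0.22 without young replicate 2 (0.372). The internal one was 0.13 with the authors' totals and 0.35 without young replicate 2 (adjusted p = 0.0474). That of the 5′ fragments of 15 to 29 nt was 0.63 without young replicate 1 (adjusted p = 0.0277), −0.29 without young replicate 2 and −0.0055 without old replicate 2. The lowest edgeR adjusted p among these 4 was 0.737.

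Across isoacceptors, 3′ fragments of 30 to 50 nt lay higher in both old libraries for 23 of 62 classes and lower for 1, against 10.3 by chance in each direction. The 3′ fragments of 15 to 29 nt lay higher for 20 of 56 and lower for 1 (9.33 by chance). The 5′ fragments of 30 to 50 nt lay lower for 21 of 46 and higher for 1 (7.67 by chance), with Trp-CCA at 558 ± 20.7 CPM in old and 945 ± 11.2 in young and Asn-GTT at 44.3 ± 3.35 and 90.5 ± 6.23 (SD, n = 2 each). The 5′ fragments of 15 to 29 nt lay lower for 4 of 51 and higher for 0 (8.50 by chance), and internal fragments higher for 12 and lower for 22 of 78 (13.0 by chance). Classes are shares of the same libraries and not independent replicates, so these counts are not a test. Median log2 fold changes by kind, in the same order, were 0.11, 0.16, −0.31, −0.07 and −0.06. Scaled to the authors' library totals, which moved the median of all classes by −0.16, the first 2 were −0.047 and −0.0097. They were −0.048 without young replicate 1 and −0.0028 without young replicate 2, in that order. The median of 5′ fragments of 15 to 29 nt was 0.28 without young replicate 1. For 5′ fragments of 30 to 50 nt the median stayed between −0.47 and −0.23 in every alternative, the authors' totals and each removed library included.

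**Figure D3:**
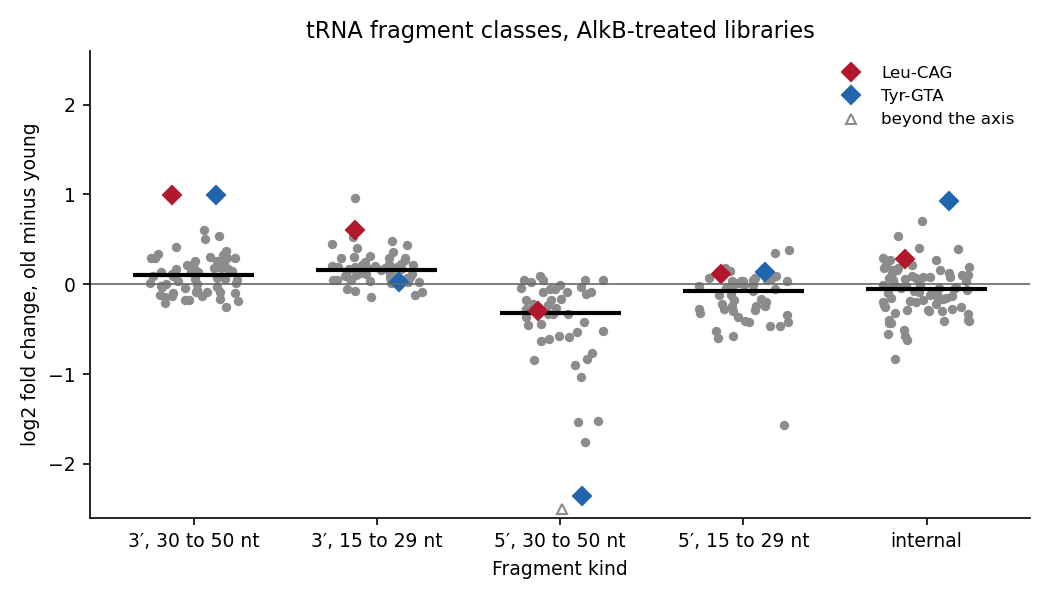
Log2 fold change (old minus young, edgeR) of each tRNA fragment class in 5 kinds, with the median of each kind as a line, Leu-CAG as red and Tyr-GTA as blue diamonds, and an open triangle for a class beyond the axis. The median of 5′ fragments of 30 to 50 nt is −0.31 and those of both 3′ kinds, 0.11 and 0.16, fall to −0.047 and −0.0097 with the authors' totals.

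Single sequences gave 0 of 22606 past the threshold by edgeR (smallest adjusted p 0.447), with 1395 at an unadjusted p under 0.05 where 1130 would be called by chance, and 52 (51 higher, 1 lower) by DESeq2. Over the 19824 sequences listed in every library and tested, a set chosen after the listing limit was seen, 45 rose and 2 fell by edgeR. Of these, 28 came from Tyr-GTA (18 internal, 10 with the 3′ end of 30 to 50 nt) and 9 from Leu-CAG (7 internal and 2 with the 3′ end). Another 3 came from Leu-CAA, all with the 3′ end. They rose by log2 1.52 (Leu-CAA-1) and by 1.49 and 1.65 (Leu-CAA-4). The 2 of Leu-CAG with the 3′ end rose by log2 1.49 and 1.48, about as much. All 9 of Leu-CAG began at position 39 and most of Tyr-GTA at the first base after base 37. Many thus share a start and overlap, and they are not independent changes. Start and end positions of the single sequences below count along the reference sequence of each tRNA, which for Tyr-GTA holds an intron. A Leu-CAG internal fragment from base 39 to 64 was at 12.6 ± 2.76 CPM in old and 2.47 ± 0.383 in young, a log2 fold change of 2.36 (SE 0.42, adjusted p = 0.0294). A Tyr-GTA internal fragment from position 58 to 77 of the Tyr-GTA-4 reference was at 33.0 ± 3.04 and 6.96 ± 1.59, one of 2.23 (SE 0.32, adjusted p = 0.0170). In that reference m1A was listed at A78 and not at position 58, so the fragment ends just before the methylated base. The 2 that fell were a Glu-TTC internal fragment from base 33 to 74 (13.3 ± 4.38 and 48.1 ± 10.2) and an Asn-GTT 5′ fragment from base 1 to 47 (6.82 ± 0.122 and 22.6 ± 3.52; SD, n = 2 each). The count of 47 was 1 without old replicate 1, 0 without old replicate 2, 1031 without young replicate 1 and 1238 without young replicate 2.

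Fragments that begin just after base 37, next to the anticodon, were examined after the lengths of the fragments had been seen, as CPM of listed tRNA reads without TMM factors. From Tyr-GTA such fragments (39 nt) were at 6902 ± 1112 CPM in old and 2445 ± 113 in young (SD, n = 2 each), 2.82-fold. From Leu-CAG (48 nt) they were at 3742 ± 441 and 1328 ± 81.7, also 2.82-fold. From Trp-CCA they were at 712 ± 15.4 and 390 ± 10.6, 1.83-fold, and from Leu-TAA at 3012 ± 328 and 1883 ± 378, 1.60-fold. Over 33 isoacceptors the median log2 ratio was 0.20 for the 12 with G at base 37 and −0.13 for the 21 with A (permutation p = 0.00086). Without Tyr-GTA and Leu-CAG, whose rise prompted the test, the medians were 0.15 and −0.13 (permutation p = 0.0155). These tests permuted isoacceptors of the same libraries, so spread between libraries did not enter. Both old libraries lay above both young ones for 8 of the 12 and for 3 of the 21 (1 in 6 by chance), the 3 being Ala-TGC (log2 0.24), Lys-CTT (0.20) and Gly-TCC (0.11). Lys-TTT, with A37, was at −0.18 as a whole, while 2 of its sequences that begin just after base 37 were among the 45 that rose above, those of Lys-TTT-2 (log2 1.43, adjusted p = 0.0170) and Lys-TTT-3 (log2 1.32, adjusted p = 0.0484). Phe-GAA, whose G37 carries the bulky base wybutosine, was at 0.05, and Pro-TGG and Arg-CCG, both with G37, were at −0.26 and −0.13. Base 37 of Tyr-GTA was placed through the 39-nt length, because its reference sequences hold an intron. Other tRNAs whose reference holds an intron were left out, and Leu-CAA was not among the 33.

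**Figure D4:**
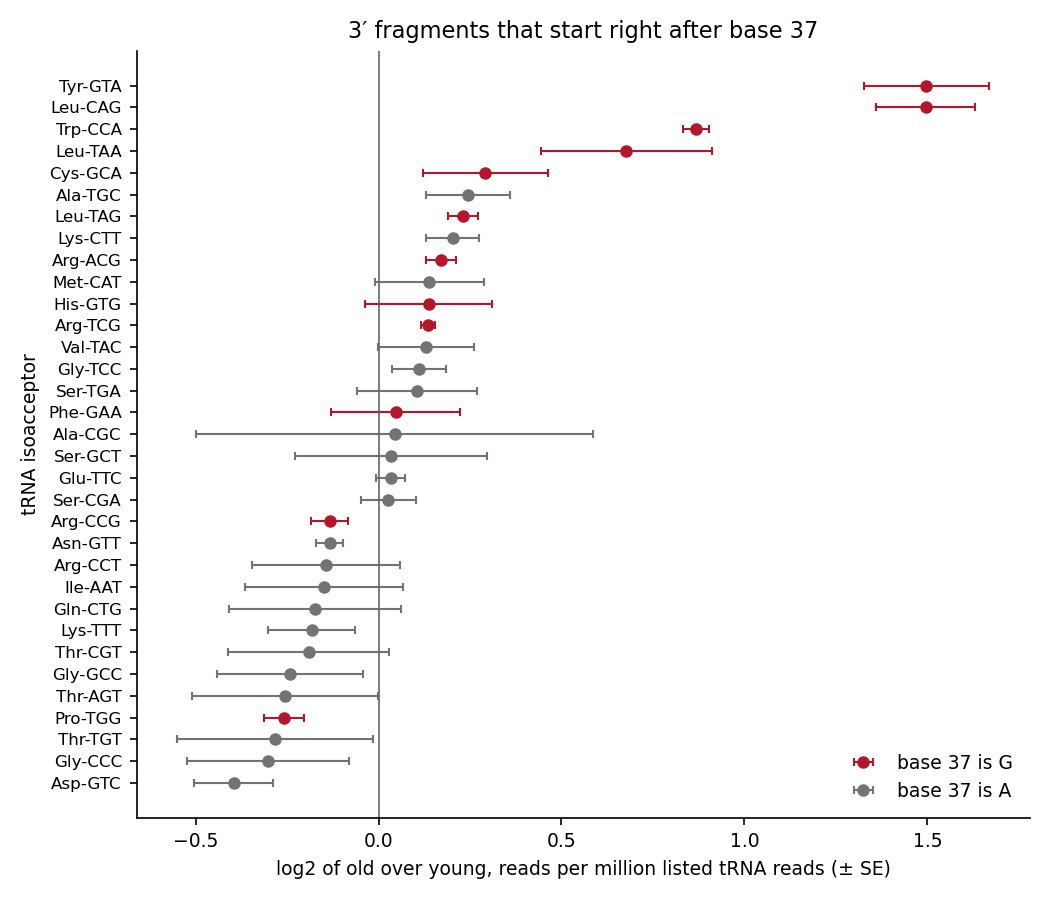
Log2 ratio of old to young CPM (± SE) of 3′ fragments that begin just after base 37, for 33 isoacceptors, red with G and grey with A at base 37. Tyr-GTA and Leu-CAG lie highest, at 2.82-fold each, above Trp-CCA at 1.83-fold and Leu-TAA at 1.60-fold.

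The untreated libraries asked whether m1A on tRNA differs with age. The level is the percent of reads that do not read A at a methylated adenine in the IP library. The input library listed with it was taken as the background, though the labels do not say how either was treated. In all 4 libraries 178 sites were listed and tested, of 193 listed in any, and 167 of them lay 18 nt from the 3′ end, the T-loop position known as A58. The mean level was above 80% at 95 sites and below 50% at 16. Arg-TCT had a mean of 94.8% over 4 sites, Leu-TAA 91.8% over 2, Leu-CAG 73.7% over 4, Ala-TGC 52.5% over 8 and Asp-GTC 45.2% over 4. Input levels averaged 2.47% and 2.70% in old replicates 1 and 2, and 3.41% and 2.65% in young replicates 1 and 2. Among misread bases, T made up 54.5% to 54.9%, G 32.1% to 32.9% and C 12.5% to 13.2%.

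The mean level per library was 77.3% and 78.3% in old replicates 1 and 2 and 75.6% and 77.9% in young replicates 1 and 2. The difference of 1.01 points lay within the spread of the young libraries (exact permutation p = 0.667), and it was −0.144 points without young replicate 1, 2.17 without young replicate 2, 1.54 without old replicate 1 and 0.484 without old replicate 2. With all libraries it was 2.44 points as the median over sites (exact permutation p = 0.667) and 0.365 weighted by reads (exact permutation p = 1). Both old libraries lay above both young ones at 44 sites and below at 12, where chance gives 29.7 in each direction, and sites are not independent replicates. Without young replicate 1, both old libraries lay above the remaining young one at 49 sites and below at 63. By the quasi-binomial model 0 sites passed (smallest adjusted p 0.404), with 7 at an unadjusted p under 0.05 where 8.90 would be called by chance. By limma on the empirical logit, 3 sites rose and 1 fell. Thr-AGT-5 A59 was at 88.5% ± 0.358 in old and 78.7% ± 4.52 in young, Lys-TTT-3 A58 at 80.1% ± 1.31 and 69.6% ± 1.73, Gly-CCC-3 A56 at 89.1% ± 2.23 and 82.5% ± 4.60, and iMet-CAT-3 A57, of initiator tRNA, at 52.5% ± 5.24 and 68.5% ± 2.54 (SD, n = 2 each). Limma gave each of these sites an SE of 0.165 on the logit, so a site's own spread did not enter. Limma's adjusted p-values were 0.00265, 0.0377, 0.0427 and 0.00464, and the quasi-binomial model gave 0.914 for each. Over the alternatives that kept all libraries, they ran from 5.07e-77 (Fisher) to 0.923. Fisher's exact test on summed reads, which ignores the spread between libraries, called 139 sites (115 higher, 24 lower).

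Sites of Leu-CAG, the tRNA whose 3′ fragments shared the smallest edgeR adjusted p, did not pass by either model. Leu-CAG-3 A68 was at 70.2% ± 1.37 in old and 64.2% ± 5.37 in young, Leu-CAG-1 A68 at 66.9% ± 0.570 and 64.9% ± 7.28, and Leu-CAG-2 A68 at 70.6% ± 1.61 and 69.4% ± 7.94 (SD, n = 2 each). Leu-CAG-4 A68 was at 91.8% ± 0.422 and 91.9% ± 2.20. Without young replicate 1, the logit differences of Leu-CAG-1 and Leu-CAG-2 were −0.14 and −0.24. The sites of Asp-GTC did not all go 1 way. Asp-GTC-2 A57 was at 44.6% ± 0.876 and 48.3% ± 0.0241 and Asp-GTC-4 A57 at 29.03% ± 3.99 and 27.8% ± 1.47, while Asp-GTC-2 A9 was at 52.7% ± 4.40 and 61.2% ± 8.41 and Asp-GTC-4 A9 at 44.7% ± 8.90 and 53.7% ± 3.10. The ages overlapped at Asp-GTC-4 A57 and Asp-GTC-2 A9, and none of the 4 passed the quasi-binomial threshold (adjusted p = 0.914 to 0.962). The lowest coverage in any library was 3517 reads at Leu-CAG-3 A68, 24195 at Leu-CAG-1 A68, 110755 at Asp-GTC-2 A57, 156 at Asp-GTC-4 A57, 31830 at Asp-GTC-2 A9 and 542 at Asp-GTC-4 A9. Over the whole set, the 10 largest rises in mean level ran from 5.99 to 10.6 points and the 10 largest falls from −16.0 to −3.31 points.

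**Figure D5:**
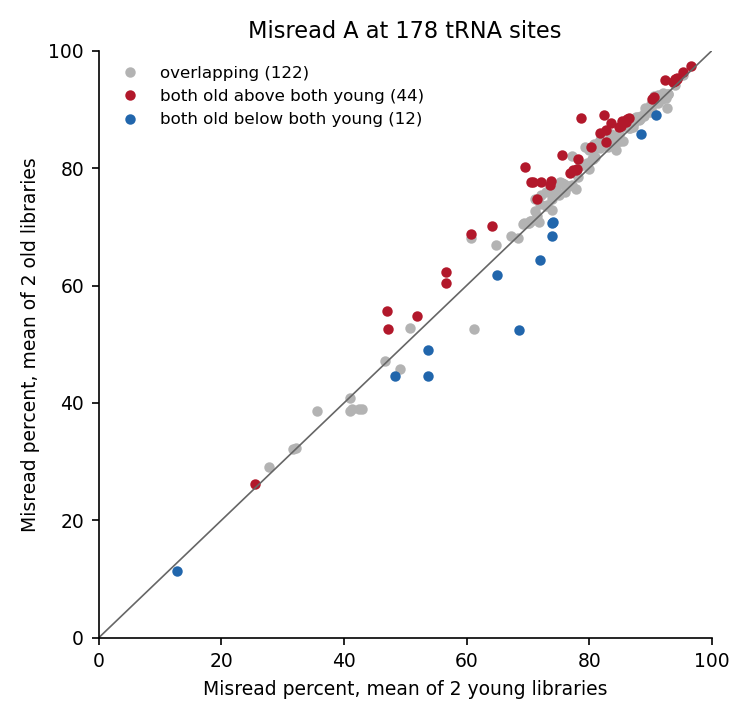
Mean percent of reads not reading A in old against young libraries at 178 sites, coloured by whether both old libraries lay above both young (44), below both (12) or overlapped (122). Most points follow the diagonal, and iMet-CAT-3 A57 lies farthest below it at 52.5% in old and 68.5% in young.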

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

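The tests of fragments that begin after base 37, of fragments that begin after A58, of G37 against A37, of input reads in the IP library and of exchanged labels were chosen only after the result was seen. The fragment files also held reads of small nuclear RNA, which entered no comparison. They made up 6.46% of listed reads in old replicate 1 (95% Wilson interval 6.44 to 6.47), 5.39% in old replicate 2 (5.38 to 5.41), 6.68% in young replicate 1 (6.65 to 6.70) and 5.60% in young replicate 2 (5.58 to 5.63), with Rnu6 giving 26.0% to 27.8% of them.

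The 3′ fragments of Tyr-GTA and Leu-CAG that begin just after base 37 were 2.82-fold higher in old cells. They exceeded the other 3′ fragments of 30 to 50 nt of the same tRNA by log2 0.81 (SE 0.23) and 0.86 (SE 0.11). That argues against a greater amount of these tRNAs as the cause of the excess. It does not bear on the rise of the other fragments themselves, at log2 0.68 (Tyr-GTA) and 0.63 (Leu-CAG). The reference sequences of Tyr-GTA hold an intron, so its fragments that cross the splice junction may be missing from this comparison. The share of m1A-site coverage on Tyr-GTA had log2 differences of 0.18 (SE 0.05) in IP and −0.0013 in input libraries, below the bound set beforehand. That argues against a rise of Tyr-GTA tRNA of that size in the m1A libraries only. It leaves a smaller rise, or one in the AlkB-treated libraries, open, since the young mice differed in age. A cap on coverage is also possible, since 3 to 5 sites per library lay above 900000 reads and none above 991089. The share on Leu-CAG, at 0.49 (SE 0.19) in input and −0.01 in IP libraries, leaves more Leu-CAG tRNA open. A general shortfall of AlkB in the old libraries also stays open, since fragments that begin after A58 had a log2 difference of 0.13 with an SE of 0.31. A candidate explanation is a stop of the reverse transcriptase at a modified G37, such as 1-methylguanosine. Without Leu-CAG and Tyr-GTA, whose rise prompted the test, isoacceptors with G37 lay log2 0.29 above those with A37 (permutation p = 0.0155). With them the gap was log2 0.33 (permutation p = 0.00086). The permutations moved isoacceptors of the same libraries, so they did not measure spread between libraries. Yet 2 sequences of Lys-TTT, with A37, that begin just after base 37 rose as well (log2 1.43 and 1.32). Some Tyr-GTA sequences that begin elsewhere also rose, such as positions 59 to 93 and 58 to 93 of Tyr-GTA-1 (log2 1.40 and 1.13). A stop at base 37 alone would not give these. The labels say that the reverse transcriptase differed between samples without saying which had which, so it stays open whether the enzyme differed with age, and a biological change with age in tRNA cleavage or in G37 methylation stays open as well, untested.

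At the m1A sites, both old libraries lay above both young ones at 44 and below at 12. Young replicate 1 was the lowest of the 4 libraries at 123 of 178 sites and had the highest input misreading at 123, where 44.5 would be so by chance. Against young replicate 2 alone, both old libraries lay above at 43.75% of the sites where they fell on 1 side (49 above, 63 below), and against young replicate 1 alone at 88.0% (132 above, 18 below), so the excess may come from that 1 low library. Reads of the input library within the IP library of young replicate 1 cannot be told apart from other causes, because the share of misread reads lost was 1.88% at 38 sites of at least 90% (bootstrap interval 1.21 to 2.32) and 0.0752% at 31 sites under 70% (−5.45 to 6.90), a ratio of 25.01 with a wide interval. The level is a rate of misreading, and the labels say that the reverse transcriptase differed between samples without saying which had which. It therefore stays open whether the enzyme differed with age or in young replicate 1. A higher m1A level with age was not excluded, and the young mice of these libraries were 8 weeks old and not 3 months.

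Trmt6 and Trmt61a did not separate the libraries labelled TG from those labelled WT. An exchange of a TG and a WT label stays open: 0 pairs of libraries held the 2 highest values of both genes, which libraries with gaps of this size would give with right or with exchanged labels. Xist split as the labels do (4.61 and 8.31 RPKM in TG, 0.0672 and 0 in WT) and the WT libraries correlated at 0.898, but neither is known to follow the transgene, so they do not decide it. The TG libraries correlated at 0.719, below every pair of a TG and a WT library (0.769 to 0.819). The spread between libraries of 200 cells may account for it: among genes of like mean expression, 14.3% of 2023 had a gap within a group at least as large as that of Trmt6 (log2 2.62) and 15.7% of 2083 one as large as that of Trmt61a (log2 2.56). The RPKM show no excess of either transcript shared by both TG libraries, and protein and transcripts outside the annotated genes were not measured here.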

How the results depend on the processing

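The scaling of RPKM by median ratios, the mean RPKM filter, the authors' library totals, the crossed block and the sequences listed in every library were chosen after seeing the data; the other alternatives were not. Alternatives that need counts (RLE, library size, a minimum of 50 counts, DESeq2 and voom) were not run for TG against WT, because the values used were RPKM. The count of TG against WT genes stayed at 0 by limma in each of 5 alternatives that kept all libraries, with 386 to 940 genes at an unadjusted p under 0.05, and ranged from 0 to 796 with 1 library left out. The camera count of 1 list became 0 with an estimated correlation, 0 with fry and 4 (3 up, 1 down) with median-ratio scaling, and ranged from 0 to 5 with 1 library left out. The edgeR count of fragment classes, 0, became 5 with DESeq2, 2 by amino acid and 4 with a single anticodon only, stayed at 0 with RLE, library size, the authors' totals and either other filter, and ranged from 0 to 65 with 1 library left out. That of sequences became 52 with DESeq2, 13 with at least 100 counts and 47 (45 higher, 2 lower) for those listed in every library, and was 0 elsewhere. The 47 became 63 with DESeq2 and ranged from 0 to 1238 with 1 library left out. The m1A count of 0 became 139 with Fisher's exact test and 4 with limma on the logit and stayed at 0 with a coverage minimum of 5 or 100 and with each library left out. Fewer libraries, another test or another grouping made these fits; further causes were not tested.

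The replicate numbers did not pair the libraries: same-numbered deviations correlated at −0.02 (RNA-seq), −0.36 (fragment classes), −0.04 (sequences) and 0.0027 (m1A). With the replicate number as a block, 0 genes, 3 lists (2 up, 1 down), 4 fragment classes (3 higher, 1 lower), 0 sequences, 92 sequences listed in every library (84 higher, 8 lower) and 0 m1A sites passed. The block turned the direction of the lymphoid list (adjusted p = 0.973) and of Leu-CAG-4 A68 (logit difference 0.012), and no other direction. With the crossed pairing, 0 classes and 0 sequences passed.

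Of the fragment values, the authors' library totals turned the median of 3′ fragments of 30 to 50 nt to −0.047 and of 15 to 29 nt to −0.0097, Leu-CAA/Leu-CAG internal to −0.046, Leu-CAA/Leu-CAG/Leu-TAG internal to −0.028 and Leu-CAG 5′ fragments of 15 to 29 nt to −0.070 (−0.00092 with library size only). By fry the CUL4-DCAF1 list turned at adjusted p = 0.969. The log2 fold changes of the 3′ fragments of 30 to 50 nt of Leu-CAG and Tyr-GTA stayed between 0.83 and 1.09 in all alternatives and with each library left out, at adjusted p from 1.46e-20 to 1.00. Over the named genes other than Trmt6 and Trmt61a, 446 of 446 alternative values that kept all libraries had the direction and side reported. So did 87 of 96 for lists, 216 of 233 for fragment classes and 109 of 134 for m1A sites. For genes this was nearly fixed in advance, since the filters and the block cannot change a fold change and 0 genes passed in any of these fits.

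With 1 library left out, values ranged as follows, each across 0. For genes the log2 fold change ranged from −1.07 to 1.54 for Trmt6, −0.60 to 1.95 for Trmt61a, −2.39 to 0.25 for Ripk1, −0.99 to 0.91 for Ripk3, −1.45 to 2.38 for Mlkl, −0.83 to 3.03 for Cd3e, −1.23 to 1.03 for Col1a2, −1.63 to 0.18 for Dda1, −0.48 to 0.15 for Emcn and −1.49 to 1.32 for Nkg7. For fragments it ranged from −1.35 to 1.58 for Leu-AAG/Leu-CAG/Leu-TAG internal, −0.24 to 0.81 for Leu-CAA/Leu-CAG 3′ and −0.51 to 0.12 for its 5′ fragments of 15 to 29 nt, −0.078 to 0.32 for its internal fragments, −0.71 to 6.84 for Leu-CAA/Leu-CAG/Leu-TAG internal and −0.29 to 0.63 for Leu-CAG 5′ fragments of 15 to 29 nt. Medians by kind ranged from −0.048 to 0.24 (3′, 30 to 50 nt), −0.0028 to 0.32 (3′, 15 to 29 nt) and −0.45 to 0.28 (5′, 15 to 29 nt), and shares from −2.35 to 4.45, −1.86 to 2.58 and −0.3332 to 0.143 points. Logit differences ranged from −0.37 to 0.063 for Cys-GCA-9 A57, −0.14 to 0.31 for Leu-CAG-1 A68, −0.24 to 0.30 for Leu-CAG-2 A68, −0.25 to 0.17 for Leu-CAG-4 A68 and −0.50 to 0.13 for Tyr-GTA-5 A74, and the mean m1A difference from −0.144 to 2.17 points. Lists whose direction turned had adjusted p from 0.662 to 0.891 (CUL4-DCAF1), 0.283 to 0.735 (ageing), 0.662 to 0.929 (stem cell identity), 0.735 to 0.940 (autophagy), 0.0221 to 0.963 (cell cycle), 0.735 to 0.891 (lymphoid, and quiescence), 0.000614 to 0.899 (respiratory chain), 1.96e-05 to 0.891 (myeloid), 0.662 to 0.919 (necroptosis), 0.735 to 0.929 (stroma and endothelium) and 0.3329 to 0.862 (tRNA modification). The causes were not tested. Depth limits the fragment tables to sequences above about 1 RPM and is unknown for the RPKM values.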

Other observations

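The values in this part were chosen after they were seen, and no test was run on them. The base read at a methylated adenine differed between tRNAs. At the T-loop adenine of Val-AAC-1 and Val-CAC-2, G made up 83.7% and 83.1% of misread bases, while at that of Val-TAC-1 T made up 54.7% and G 28.4%. At the sites of Gly-GCC-2 and Gly-CCC-1, T made up 96.96% and 82.1%, and at Gly-ACC-1 G made up 84.6%. The level also differed between genes of 1 isoacceptor: Ser-GCT-3 A67 was at 94.6% ± 0.751 and Ser-GCT-5 A67 at 25.8% ± 0.406 (SD over the 4 libraries), with a lowest coverage of 203537 and 742 reads. Ala-AGC-3 A57 was the lowest of all sites, at 12.1% ± 1.11 with at least 14721 reads.

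Adenines outside the T-loop were few among the listed sites. Asp-GTC-2 A9 was at 56.9% ± 7.35 and Asp-GTC-4 A9 at 49.2% ± 7.52 (SD over the 4 libraries), and 91.8% and 89.2% of their misread bases were T. At Ala-TGC-6 A15 the level was 64.5% ± 6.18 and G made up 99.2% of misread bases. Input misreading there was 13.3%, 9.64%, 9.12% and 7.70% in old replicates 1 and 2 and young replicates 1 and 2.

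In the RNA-seq libraries, Rn45s, the ribosomal RNA precursor, was the highest gene in 3 of the 4 libraries, at 40381 RPKM in TG replicate 2, 51590 in WT replicate 1 and 46113 in WT replicate 2. In TG replicate 1 the highest was Rps14, a ribosomal protein gene, at 20023 RPKM.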
